A study of Oryza sativa Indica Group with 36 samples.

How the data were processed

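Mature leaves of Minghui 63, an indica rice cultivar, were profiled by RNA sequencing under a cycle of 12 h light and 12 h dark (LD), under constant light (LL) and under constant dark (DD). Each condition was sampled at ZT0, ZT4, ZT8, ZT12, ZT16 and ZT20, where ZT (zeitgeber time) counts hours from lights-on, with 2 replicates per time. This gave 18 groups, 12 libraries per condition and 36 libraries. Per the labels' protocols, RNA was isolated with a plant RNeasy kit and libraries were made with a stranded total RNA kit after plant ribosomal RNA depletion. How long the plants had stood in constant light or dark before ZT0 was not given in the sources used here. The 6 times cover a single 24 h cycle, so that a repeat of a rhythm on a further day was not measured. The labels number the replicates but do not say that they came from separate plants, and p-values then measure only the spread between these libraries, which may be technical.

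The deposited files hold whole-number counts of reads per gene ID for each library, without normalization. Per the submitters' processing notes, Trimmomatic, HISAT2, Cufflinks 2.1.1 and HTSeq were used. The genome build, the annotation, the strand setting and the other parameters were not given in the sources used here. Without the strand setting, reads of an ID and of an overlapping or antisense neighbour cannot be told apart, and IDs with near-identical copies are uncertain. Each file lists 57174 IDs and 5 further rows for reads given to no ID, which stayed out of library sizes and tests. Reads in no annotated feature made up 46.12% to 64.86% of all counted reads per library, with means of 55.43% in LD, 52.93% in LL and 62.97% in DD. Reads fitting more than a single feature made up at most 0.248%. The other 3 of these rows held 0 in all 36 libraries, so that the treatment of reads matching several places cannot be read from the deposited counts.

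The files pair no ID with a gene name. None of the IDs matched the reference table of rice genes, and 0 of the 120 genes of the lists fixed in advance (clock, flowering, photoreceptor and other groups) could be found. The planned list tests with camera and fry, and the naming of genes by symbol, were therefore not run. IDs are printed as the files give them, with no position or function. The rule for named IDs, written before the data were examined, took those with the largest fitted peak-to-trough fold per condition among IDs called rhythmic at 5 CPM or more, and those with the largest rise and fall per level comparison at 5 CPM or more with all 6 times on the same side. At most 2 were printed per direction. For rhythms, peaks in the light and in the dark part of the LD cycle took the place of directions.

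Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs were kept by filterByExpr over the 18 groups, with a minimum count of 10 and a minimum total of 15, which left 17868 tested IDs. Library sizes were scaled by TMM. A quasi-likelihood model with robust dispersion was fitted to all 36 libraries, with a mean, 24 h and 12 h cosine and sine terms and an alternating term per condition. These terms describe the 6 times in full, and the 18 residual degrees of freedom come from replicates only. An ID was called rhythmic when the F test of the 24 h cosine and sine terms gave a Benjamini-Hochberg adjusted p under 0.05. Change over time of any shape used all 5 terms apart from the mean. Levels were compared as condition means over the 6 times. Rhythm differences were tested as the difference of the 24 h terms between conditions. Peak-to-trough size, peak time and, apart from that of MH03g0044000, log2 level differences came from limma 3.58.1 on log2 CPM with a prior count of 2. Standard errors came from the same fits. The prior count pulls these values towards 0 where an ID has few or no reads. A log2 level difference then need not equal the ratio of the printed CPM means. A fold against a group with 0 counts was set against a floor of 3 counts over that group. Floors and intervals cover counting error only. The level test gave no finite estimate for some IDs with no reads at a time point. Of 1511 IDs with such a time in DD or LD, 183 were called by limma-voom and not by edgeR. For LL or LD these counts were 693 and 171.

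Total counts over gene IDs ranged from 3428326 to 14832451 in LD, from 1227617 to 3613494 in LL and from 1099066 to 3083013 in DD. Counts of replicates were compared with a chi-square test. All 18 pairs differed beyond sampling noise, with a p of at most 7.38e-90, and each library was kept as a replicate.

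The tests were tried on simulated counts of 16728 IDs. These were drawn from a single mean per ID over all 36 libraries, the library sizes and the dispersion of each condition. There were 200 changed IDs per level or rhythm comparison, 50 each at 1.5-fold, 2-fold, 4-fold and 8-fold, and 400 per rhythm difference, 100 each. Other IDs held no difference, while far more IDs were called in the data, so the numbers of false calls do not carry over to the data. The planned test of rhythms found 34 of 50 2-fold and 48 of 50 4-fold changes in LD, 14 and 47 in LL, and 17 and 40 in DD. It made 798 false calls in LD and 0 in LL and in DD, because a single dispersion was shared by conditions whose replicates differ unequally. The simulated counts held no spread between times beyond that of replicates. If LL and DD replicates are repeats of a single plant sample, differences between plants are missing there. False calls in LL and DD may then be more than simulated. Fits to the libraries of a single condition found 2 of 50 2-fold and 33 of 50 4-fold rhythms in LD with 4 false calls, 38 and 50 in LL with 9, and 32 and 48 in DD with 21. The level test found 45 of 50 2-fold changes with 35 false calls for DD against LD, and 49 of 50 with 39 for LL against LD. The test of rhythm differences found 19 of 100 2-fold changes with 51 false calls for DD against LD, 19 with 45 for LL against LD, and 6 with 0 for LL against DD. Adjusted p-values that involve LD are thus too small. For rhythms and change over time, counts from the libraries of a condition alone are given beside the planned ones. For levels and rhythm differences, counts from the compared conditions alone are given. Those fits still share a dispersion between regimes and were not tried on simulated counts. The simulated counts were redrawn with another random seed after a first draw had been seen, because the first seed was equal to a printed value, and the values here are those of the last draw. Fitted peak times of the simulated rhythms of 2-fold or more were off by a median of 0.431 h in LD, 0.24 h in LL and 0.277 h in DD.

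Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, TMM without the 20 most abundant IDs, the DESeq2 tests, limma-voom, other low-count filters, a replicate block, fits to the compared conditions alone, an adjusted p under 0.01, a cosinor regression with and without a linear trend, a 2-fold minimum, the time of the highest mean as peak time, and leaving out each library in turn. Chosen after seeing the data were thinning of all libraries to 1099066 counts, a fit without 3 LD libraries that stood apart, summed replicates, library sizes without normalization factors, and limma-voom with a weight per condition, the last after the simulated counts were seen.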

Results

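The series measured transcript levels in rice leaves over a day under 3 light regimes. The design asks which genes follow a daily rhythm in light/dark cycles, which do so in constant light or constant dark, and how levels differ between regimes. All 36 libraries held counts for the same 57174 gene IDs. Gene counts per library had a median of 10620768 in LD, 2531508 in LL and 2115978.5 in DD. From 22662 to 34598 IDs were detected in the LD libraries, 19496 to 21714 in LL and 18072 to 20257 in DD.

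The 3 regimes formed separate groups of libraries. The first principal component of log2 CPM, with 43.4% of the variance, placed the DD libraries at 112 to 141, apart from LD at -96.7 to -36.1 and LL at -77.1 to -33.3. The next component, with 17.6%, placed LD at 40.6 to 100 and LL at -82.1 to -47.4. A single ID, MH03g0044000, held 26.3% ± 2.7 of gene counts in DD (SD, n = 12), against 12.0% ± 2.65 in LD and 13.8% ± 3.93 in LL. It was higher in DD than in LD by 1.45 on the log2 scale (edgeR adjusted p = 8.56e-11) and passed no threshold in LL (edgeR adjusted p = 0.706). MH04g0643900 held 12.0% ± 0.979 in DD, 5.27% ± 1.28 in LD and 6.67% ± 1.92 in LL.

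**Figure D1:**
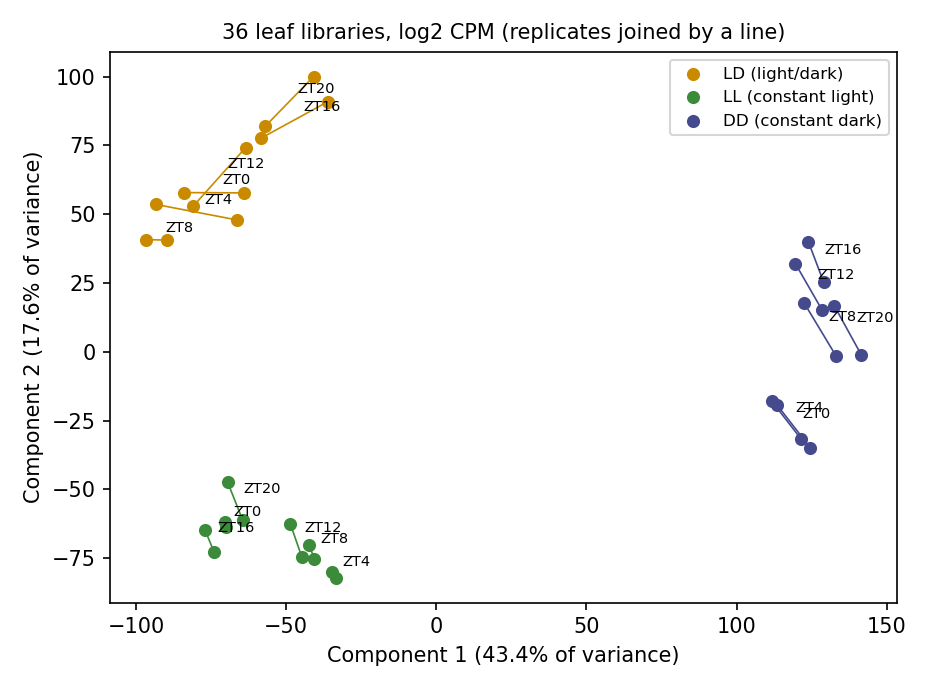
Each point is a library, with component 1 (43.4% of variance) on the x axis and component 2 (17.6%) on the y axis, coloured by condition, with the 2 replicates of a time joined by a line. The DD libraries lie at 112 to 141 on component 1, and LD and LL libraries separate on component 2.

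Replicates differed far more in LD than in the constant regimes. The biological coefficient of variation, estimated within each condition, was 31.1% in LD, 5.84% in LL and 9.52% in DD. With each library thinned to 1000000 counts, the chi-square per degree of freedom of the 6 pairs was 5.494 to 9.742 in LD, 1.168 to 1.873 in LL and 1.355 to 1.739 in DD. LD libraries were also deeper in the median, though the lowest LD library (3428326 gene counts) lay below the highest LL library (3613494). Depth and replicate spread therefore changed together with the light regime. Thinning to equal totals takes out the difference in total gene counts, and the larger spread of LD remains there. The reads left for other IDs still differ, since MH03g0044000 took a larger share in DD.

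In LD, the IDs with the largest rhythms went from a few CPM to very high levels within the day. MH09g0250600 rose from 3.57 ± 2.04 CPM at ZT20 to 6353 ± 1220 CPM at ZT8 (SD, n = 2 each), with a fitted peak at 6.89 ± 0.155 h (SE) and a peak-to-trough size of 11.54 ± 0.468 on the log2 scale (SE, edgeR adjusted p = 4.61e-15). MH07g0397700 peaked later, at 10.5 ± 0.12 h, and went from 2.74 ± 0.27 CPM at ZT0 to 3867 ± 523 CPM at ZT8 (edgeR adjusted p = 8.92e-19). MH02g0550100 peaked near the end of the night, at 23.4 ± 0.206 h, from 1.51 ± 1.08 CPM at ZT12 to 811.2 ± 190 CPM at ZT0 (edgeR adjusted p = 5.96e-14). In LD, 11326 of 17868 tested IDs (63.4%) were called rhythmic, 7619 of them with a fitted fold of at least 2 and 2732 of at least 4. This count rests on a spread shared with LL and DD, which is too small for LD. The LD libraries alone called 7716 IDs, of which 7704 were among the 11326. In simulated counts, where few IDs were changed, the planned test made 798 false calls in LD (84.9% of its calls there). LD libraries alone made 4 (4.6%). These shares do not carry over to the data, where far more IDs were called.

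All 3 of these IDs kept a rhythm in the constant regimes, with a smaller fitted size. They were chosen for their large fitted fold in LD, which favours a larger size in LD and small p-values for a difference. The size of MH09g0250600 was 4.16 ± 0.11 on the log2 scale in LL and 4.80 ± 0.217 in DD (SE), that of MH07g0397700 was 4.51 ± 0.0622 and 2.88 ± 0.0924, and that of MH02g0550100 was 4.34 ± 0.196 and 1.92 ± 0.238. The rhythm of MH09g0250600 differed from LD in LL (edgeR adjusted p = 1.43e-10) and in DD (1.06e-11). The same held for MH07g0397700, with adjusted p of 6.97e-13 and 1.02e-14, and for MH02g0550100, with 1.84e-09 and 5.98e-10. The fitted peak of MH09g0250600 lay at 5.41 ± 0.101 h in LL and 3.59 ± 0.173 h in DD. That of MH07g0397700 lay at 10.1 ± 0.0526 h and 12.3 ± 0.122 h, and that of MH02g0550100 at 20.4 ± 0.173 h and 23 ± 0.474 h.

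**Figure D2:**
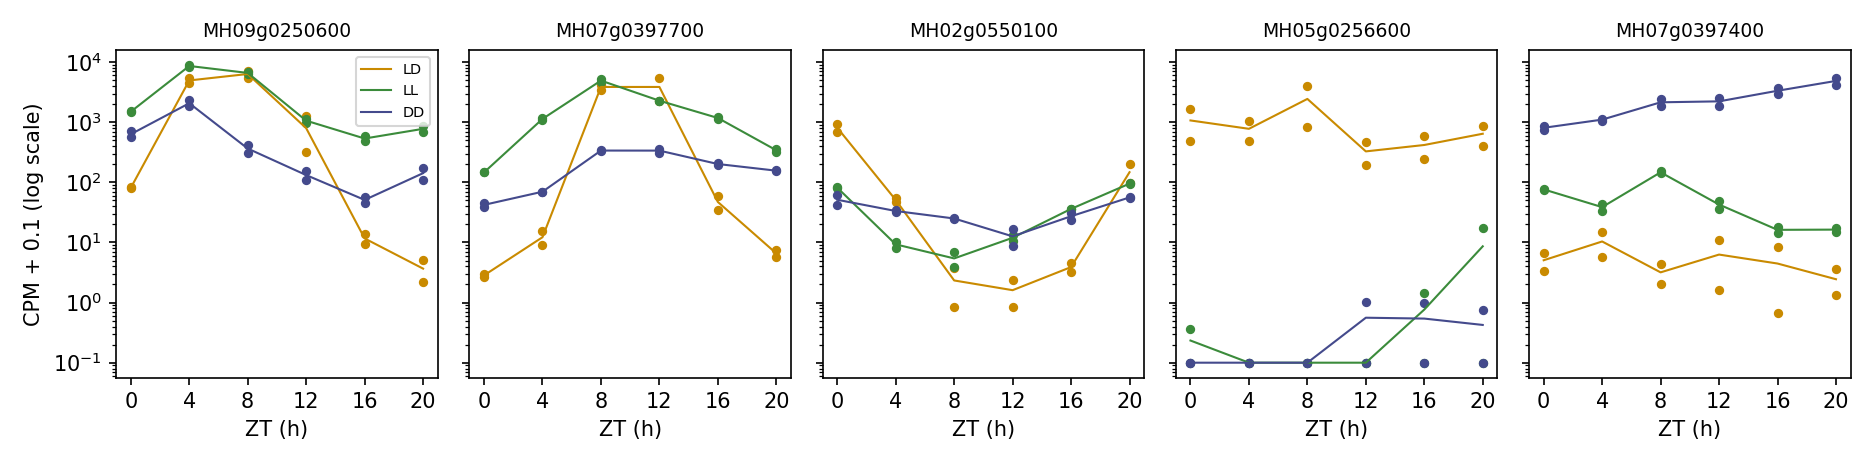
CPM + 0.1 on a log axis against ZT in h for 5 IDs, with a point per library, a line through the mean of the 2 replicates and a colour per condition. The first 3 panels show the LD rhythms with the largest fitted fold, MH05g0256600 lies near 0 in LL and DD apart from 17.1 CPM in replicate 1 of LL at ZT20, and MH07g0397400 averages 2417 CPM in DD against 5.206 in LD.

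In LL, the largest rhythms that peaked in the light part of the LD cycle belonged to IDs that were silent for part of the day. MH10g0395300 had 0 counts in both libraries at ZT4 and 37.61 ± 2.66 CPM at ZT12 (SD, n = 2), at least 35-fold higher than the floor of 3 counts (edgeR adjusted p = 0.0029), and limma-voom did not call this rhythm. In LD its presence differed between libraries of the same time, with 1 and 231 counts in the replicates at ZT0, 0 and 225 at ZT8, and 1 and 130 at ZT16. MH09g0013200 had 0 counts at ZT4 and 35.13 ± 2.81 CPM at ZT12, at least 33-fold higher (edgeR adjusted p = 7.01e-08). MH07g0075300 peaked at 23.2 ± 0.245 h, with 3 counts at ZT8 and 21.99 ± 2.94 CPM at ZT0, a ratio of 47 (95% counting interval 15.8 to 230, edgeR adjusted p = 6.17e-06). In LL, 4397 IDs (24.6%) were called rhythmic, 2858 of them at least 2-fold. The LL libraries alone, with their small spread, called 8714, and these held 4393 of the 4397.

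In DD, the same pair of IDs peaked in the earlier part of the cycle. MH10g0395300 reached 205.2 ± 44.2 CPM at ZT8 and had 0 counts at ZT16, at least 316-fold lower (edgeR adjusted p = 0.000553), and the cosinor regression did not call it. MH09g0013200 reached 83.1 ± 0.171 CPM at ZT4 and had 0 counts at ZT16, at least 129-fold lower (edgeR adjusted p = 1.92e-08). MH06g0057800 went from 1 count at ZT4 to 640.8 ± 146 CPM at ZT20, a ratio of 1890 (95% counting interval 339 to 74800, edgeR adjusted p = 4.89e-13). Its replicates already held 291.7 and 459.5 CPM at ZT8, and its highest mean was at ZT20, though the fitted peak lay at 14.3 ± 0.138 h (SE). No fall was sampled after this rise, so a one-way change cannot be told from a daily rhythm for this ID. MH04g0100000 had 0 counts at ZT0 and 53.75 ± 8.94 CPM at ZT16, at least 47-fold higher (edgeR adjusted p = 5.05e-06). With replicates summed, a setting chosen after seeing the data, the LL and DD rhythms of MH10g0395300 and MH09g0013200 and the DD rhythm of MH06g0057800 missed the threshold. In DD, 4666 IDs (26.1%) were called rhythmic, 3027 of them at least 2-fold. The DD libraries alone called 7034, among them 4617 of the 4666.

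The order of the regimes by number of rhythmic IDs depends on whose spread is used. With a spread shared by all libraries LD had the most calls, and with each regime's own libraries LL had the most. With replicates summed and the spread taken from departures from a cosine, the counts were 6616 in LD, 760 in LL and 881 in DD. With every library thinned to 1099066 counts they were 7481, 3658 and 3726. Both of the last settings were chosen after seeing the data.

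**Figure D3:**
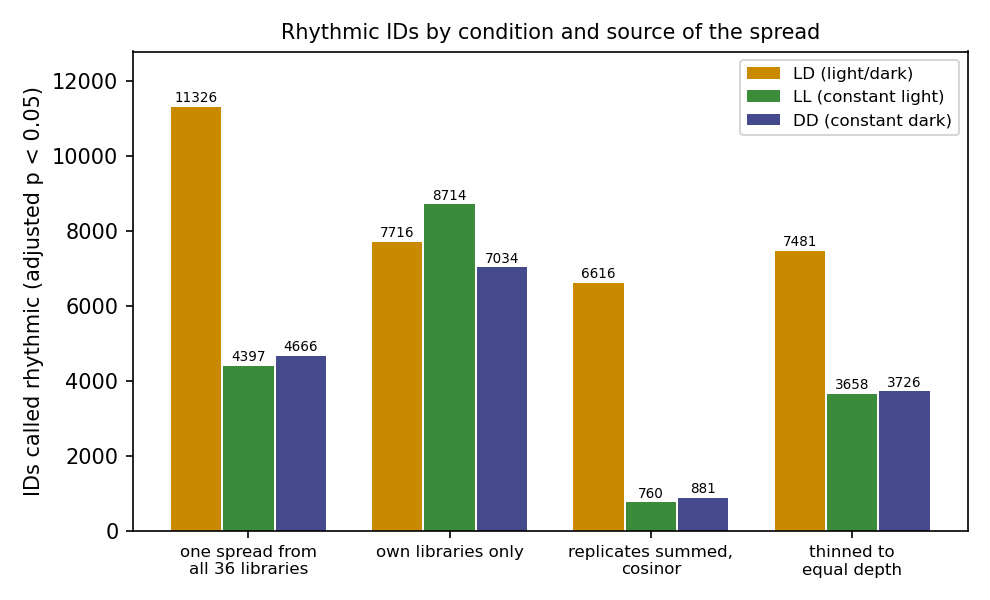
Number of IDs called rhythmic (y axis) in LD, LL and DD (bars) for 4 sources of the replicate spread or depth (x axis). LD has the highest bar with a shared spread (11326), and LL has the highest bar when each regime's own libraries are used (8714).

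Rhythmic IDs were shared between regimes more often than independent lists would be. LD and LL shared 3633 IDs where independent lists share 2787 (odds ratio 3.57, 95% CI 3.28 to 3.89), and LD and DD shared 3379 against 2958 (1.74, 1.61 to 1.87). LL and DD shared 1865 against 1148 (2.81, 2.61 to 3.02). All 3 regimes called 1597 IDs rhythmic, where independent lists give 727.8. With each regime's own libraries the shared set held 2513 IDs against 1481. The odds ratios were then 2.47 for LD with LL, 1.39 for LD with DD and 2.78 for LL with DD. These are counts over IDs, which are not independent replicates. In the planned fit the 3 tests of an ID share its dispersion, so IDs with a small spread tend to pass together. IDs with many reads also pass more easily in every regime, with own libraries as well. Part of the excess over independent lists can therefore come from the tests, and how much was not tested.

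Change over time of any shape was called for 10941 IDs in LD, 4586 in LL and 4230 in DD (edgeR, adjusted p under 0.05). The LD libraries alone called 5256. In simulated counts, where few IDs were changed, the planned test made 2137 false calls of this kind in LD (93.6% of its calls there). That share does not carry over to the data. The LL libraries alone called 10163 and the DD libraries alone 7165. Of the IDs so called with the planned fit, 808 in LD, 977 in LL and 726 in DD were not called rhythmic.

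Levels of most IDs differed between DD and LD, in both directions. MH04g0666800 averaged 549.2 CPM in DD and 0.068 in LD, with 11 LD counts in all. Its fitted difference was 9.52 ± 0.118 on the log2 scale (SE, n = 12 libraries each, edgeR adjusted p = 2.57e-29). MH07g0397400 averaged 2417 CPM in DD against 5.206 in LD (8.92 ± 0.322, edgeR adjusted p = 8.35e-15). MH05g0256600 averaged 0.204 CPM in DD, with 5 counts in all, and 947.4 CPM in LD, a fitted log2 difference of -10.36 ± 0.326 (edgeR adjusted p = 1.86e-12). MH03g0585800 averaged 0.39 CPM in DD, with 9 counts in all, and 182.2 in LD (fitted log2 difference -8.11 ± 0.323, edgeR adjusted p = 1.99e-13). With so few reads in the lower regime, the sizes for MH04g0666800, MH05g0256600 and MH03g0585800 depend on the prior count of 2. Their SE do not cover this. All 4 lay on the same side at each of the 6 times. In all, 6072 IDs were higher and 7866 lower in DD than in LD, of which 3282 and 4453 differed at least 2-fold. The median log2 difference over tested IDs was -0.171. With library sizes and no normalization factors, a scaling chosen after seeing the data, 4513 were higher and 9729 lower, and the median was -0.472, so the balance of directions depends on the scaling. In simulated counts this test made 35 false calls.

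Levels also differed between LL and LD in both directions, and fewer IDs were at least 2-fold lower in LL than were so in DD. MH06g0615000 averaged 39.4 CPM in LL and 0.742 in LD (4.97 ± 0.225 on the log2 scale, SE, n = 12 libraries each, edgeR adjusted p = 1.14e-14), and MH03g0305900 averaged 43.43 CPM against 1.19 (4.92 ± 0.214, edgeR adjusted p = 1.68e-17). MH05g0256600 and MH03g0585800 were low here too, with log2 differences of -10.06 ± 0.493 and -7.58 ± 0.41 (edgeR adjusted p = 2.42e-12 and 1.99e-13). Of the 68 LL counts of MH05g0256600, 64 came from replicate 1 at ZT20, and of the 37 of MH03g0585800, 28 came from that library. Both sizes therefore depend on the prior count as well. In all, 6146 IDs were higher and 6535 lower in LL than in LD, of which 2790 and 2075 differed at least 2-fold. With DESeq2 size factors 6473 were higher and 6202 lower, so neither direction led under every scaling. The LL and LD libraries alone called 12379 IDs in level, against 12681 with the planned fit. In simulated counts, where few IDs were changed, this test made 39 false calls, 17.3% of its calls there.

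The direction of these level differences varied with the time at which an ID peaked in LD. This tally was made after the data were examined, over IDs that are not independent. Of the 1482 IDs with an LD peak between ZT4 and ZT8, 50.2% were higher and 21.4% lower in LL (odds ratio for higher among called IDs, against the other LD rhythmic IDs, 2.83, 95% CI 2.46 to 3.26). In DD 24.2% of them were higher and 56.3% lower (odds ratio 0.51, 0.446 to 0.582). Of the 1928 IDs that peaked between ZT20 and ZT24, 25.8% were higher and 51.7% lower in LL (odds ratio 0.462), while 46.9% were higher and 35.5% lower in DD (odds ratio 1.91). For LL these directions held under all 4 scalings. For DD the late-night group turned to 35.0% higher and 46.0% lower with library sizes only, and its odds ratio stayed above 1 at 1.80. The DD group at ZT16 to ZT20 turned with library sizes only and also with LD calls from LD libraries only, from 43.1% higher and 39.0% lower to 40.5% and 43.5% with the latter.

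**Figure D4:**
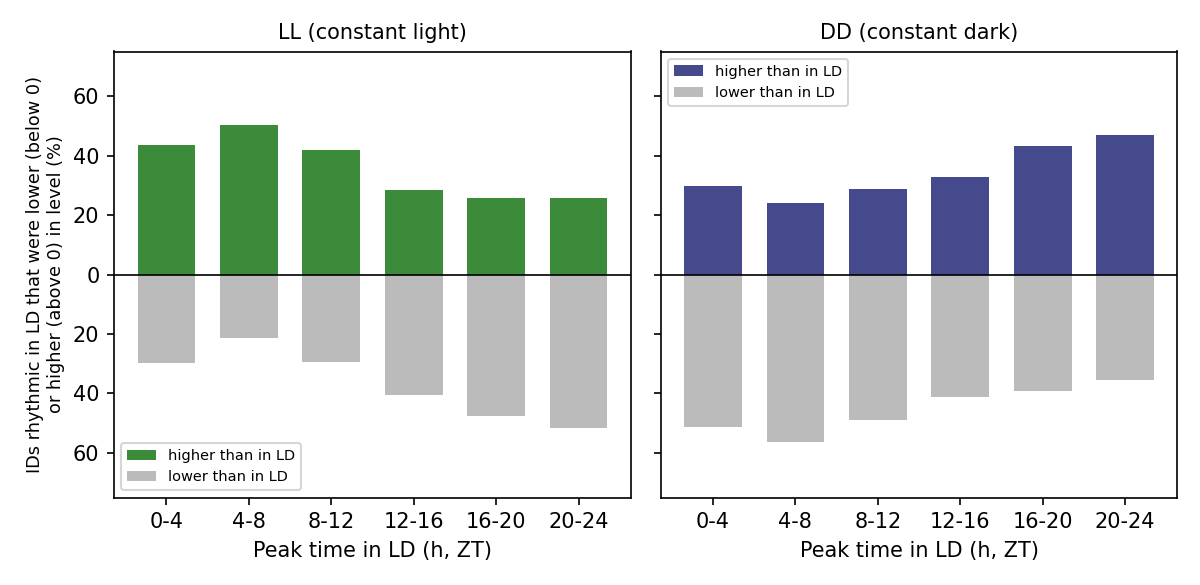
Share of LD rhythmic IDs (y axis, %) that were higher (above 0) or lower (below 0) in LL or DD than in LD, by their peak time in LD (x axis, h). IDs that peak at ZT4 to ZT8 are 50.2% higher in LL and 56.3% lower in DD, and in DD the balance at ZT16 to ZT24 turns with library sizes only, at ZT16 to ZT20 also with LD calls from LD libraries only.

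Rhythms themselves differed between regimes for 7630 IDs in DD against LD, 6922 in LL against LD and 3683 in LL against DD (edgeR, adjusted p under 0.05). The fitted size was smaller in DD than in LD for 68.8% of the first set and smaller in LL than in LD for 81.5% of the next. For LL against DD it was smaller in LL for 58.8%. Over the 1390 IDs rhythmic in all 3 regimes and at 5 CPM or more in each, the median size was 1.69 on the log2 scale in LD, 1.15 in LL and 1.16 in DD. Choosing IDs by their LD rhythm favours LD. Among the 3332 IDs above this level chosen by their LL rhythm the size was still smaller in LL than in LD for 61.4%, and among the 3608 chosen by their DD rhythm it was smaller in DD for 46.1%. In simulated counts the test made 51 false calls for DD against LD (21.4% of its calls there) and 45 for LL against LD (18.6%). Few IDs were changed there, so these shares do not carry over to the data. False calls from the larger LD spread would tend to be larger in size in LD. They may add to the 68.8% and 81.5%, and by how much was not tested. For simulated rhythms of 2-fold or more, the median error of the fitted size in LD was 0.00779 on the log2 scale.

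Fitted peak times spread over the whole cycle in LD and LL and gathered in DD, which the times of the highest mean showed less clearly. In LD the share of rhythmic IDs per 4 h bin ranged from 13.1% at ZT4 to ZT8 to 18.8% at ZT16 to ZT20, and in LL from 12.0% at ZT0 to ZT4 to 20.3% at ZT8 to ZT12. In DD 29.5% peaked at ZT0 to ZT4 and 30.5% at ZT12 to ZT16. The DD libraries alone gave 27.3% and 29.0%. By the time of the highest mean, DD had 27.3% at ZT0, 11.3% at ZT12 and 22.8% at ZT16, LL had 22.3%, 12.0% and 23.4%, and LD had 10.2% to 23.2% per time. Over IDs rhythmic in both regimes, the median fitted peak was earlier in LL than in LD by a shift of -2.3 h, with -2.65 h in replicate 1 and -2.0 h in replicate 2. For DD against LD it was -2.15 h, with -2.7 h and -1.9 h, and -1.0 h over IDs at least 2-fold in both and -1.4 h over IDs rhythmic in all 3 regimes. Single IDs varied widely around this, with quartiles of -6.57 h and 1.47 h and 26.8% within 2 h. For LL against DD the shift of 0.75 h was about as large as the SD between replicates (0.742 h), which gave 0.8 h and -0.25 h, of opposite sign. The LL against DD shift turned to -1.1 h over IDs rhythmic in all 3 regimes and -1.55 h over IDs at least 2-fold in both. Calls from each regime's own libraries gave -2.35 h for DD against LL over 4498 IDs, so the direction depends on the IDs taken. When the time of the highest mean stood for the peak, in steps of 4 h, all 3 median shifts were 0 h.

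**Figure D5:**
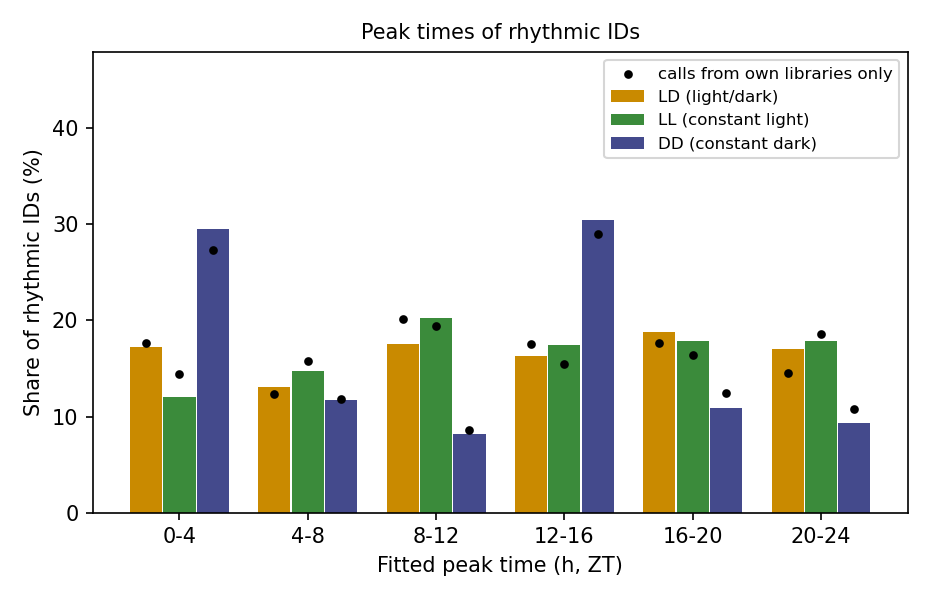
Share of rhythmic IDs (y axis, %) by fitted peak time (x axis, 4 h bins of ZT) in LD, LL and DD (bars), with dots for calls from the regime's own libraries only. DD shows 29.5% at ZT0 to ZT4 and 30.5% at ZT12 to ZT16.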

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

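The plain splits were set down before their result was seen. The splits with levels taken out and those by whole times were chosen after it, and the thinning of removed IDs was chosen after their counts were seen. The rhythm of 7630 IDs in DD and of 6922 IDs in LL differed from that in LD, and that of 3683 IDs differed between LL and DD, each by a test of the difference itself. In the planned splits, libraries were exchanged singly between the compared regimes within each time, in 100 splits with the real included. For DD against LD 1 of 100 reached the real count (highest other 7009), for LL against LD 1 of 100 (5289) and for LL against DD 4 of 100 (5158, above the real 3683). Differences between regimes add to the replicate spread of mixed groups there and favour the real split. Taking out each ID's level difference gave 1 of 100 for each, with the same weakness for mixed groups. Splits that exchange both libraries of a time leave the replicate spread untouched. With levels taken out, 1 of the 32 such splits of the libraries reached the real 7539 for DD against LD (highest other 5477, median 2366). For LL against LD 1 of 32 reached 6942 (5394, 2510), and for LL against DD 1 of 32 reached 3549 (2622, 896). By these splits chance can be excluded at a share under 0.05, though not an effect of handling shared by a regime's libraries. Fits to the compared libraries alone called 6256 rhythm differences for DD against LD and 6147 for LL against LD, fewer than planned. For LL against DD they called 6829, more than planned. In DD against LD the fitted size was smaller in DD for 68.8% of the called IDs, and for LL against LD it was smaller in LL for 81.5%. False calls from the larger replicate spread of LD may add to both shares.

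Some reads fell on IDs that the low-count filter had removed. In replicate 1 of LD at ZT12, 16886 of 39306 removed IDs had a read, together 0.584% of that library's gene counts. Replicate 2 of the same time had 12687, and the other LD libraries had 5448 to 9980. With every library thinned to 1099066 counts, replicate 1 still had the most, with 4711 against 2894 in replicate 2. No explanation of this was tested.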

How the results depend on the processing

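Thinning, summed replicates, library sizes only, the weights per condition and the fit without 3 LD libraries were chosen after seeing the data. For 12 counts of called IDs, DESeq2 size factors, DESeq2 tests, TMM without the 20 most abundant IDs, library sizes only, both other filters and the fit without the 3 LD libraries moved none by over 1.5 times. List tests were not run, since no ID had a name. Replicate numbers were not treated as pairs: deviations of same-numbered libraries correlated at -0.227 to 0.521, over 0.1 for 7 of 153 pairs of groups. All 7 were among the 15 LD pairs (median 0.0966), and replicate 2 lay above replicate 1 on component 1 at all 6 LD and all 6 DD times, so the spread is not wholly free of the number. With a replicate block the rhythmic counts were 11509 in LD, 4587 in LL and 4805 in DD, and no count moved by over 1.5 times with that block or a block within condition. Named IDs were chosen for large effects, which favours keeping a call. Of 946 values of named IDs under alternatives, 648 came from leaving out a library. Of all 946, 939 kept their call, 7 missed the threshold and 0 turned. These were LL and DD rhythms, of MH10g0395300 under limma-voom (LL, log2 size 6.91), under the cosinor regression (DD, 9.16) and with summed replicates, and of MH09g0013200 and MH06g0057800 with summed replicates.

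The counts below are in the order rhythmic in LD, LL, DD and all 3, changing over time in LD, LL and DD, level DD and LL against LD, and rhythm difference DD and LL against LD and LL against DD, as far as named. An adjusted p under 0.01 gave rhythmic LL 2697, DD 2686 and all 3 787, time LL 2788 and DD 2390, and difference LL against LD 4587 and LL against DD 2016, by the threshold itself. A 2-fold minimum gave rhythmic LL 2858, DD 3027 and all 3 764, and levels 7735 and 4865, by construction. Limma-voom gave rhythmic DD 3105, all 3 1025 and time DD 2535, and the cause was not tested. The cosinor regression gave 842 rhythmic in all 3. With a linear trend, which takes up part of a single cycle, it gave rhythmic LL 2385, DD 1255 and all 3 311, and differences 4205, 3651 and 798. Summed replicates, with fewer samples and another source of spread, gave rhythmic LD 6616, LL 760, DD 881 and all 3 100, and differences 2782, 1961 and 510. Thinned libraries, with fewer reads, gave rhythmic LD 7481 and time LD 7075. The compared libraries alone, with their own spread, gave rhythmic LL 8714, DD 7034 and all 3 2513, time LD 5256, LL 10163 and DD 7165, and difference LL against DD 6829. Weights per condition gave rhythmic LL 8339 and all 3 2523, time LD 6402, LL 10001 and DD 6741, and difference LL against DD 6672. The time of the highest mean gave 0 h for all 3 peak shifts, in steps of 4 h.

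Leaving out each of the 36 libraries in turn, where the lone library of a group is taken to vary like the others, moved no count by over 1.5 times and ended no call of a named ID. Rhythmic counts ranged from 10620 to 11284 in LD, 3413 to 4737 in LL, 3555 to 5077 in DD and 1302 to 1757 in all 3. Time counts ranged from 10380 to 11450, 3439 to 5021 and 3107 to 4626, levels from 13570 to 13913 and 12283 to 12760, and differences from 6898 to 7904, 6140 to 7421 and 2993 to 4003. In simulated counts of 16728 IDs the planned test found 14 of 50 2-fold rhythms in LL and 17 of 50 in DD, where fits to the libraries of the regime alone found 38 and 32.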

Other observations

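The tests of like-patterned on-off IDs, of equal depth and of library repeats were chosen after their results had been seen in part, and those of circular orders, planned splits, neighbours and genotype at the DD peaks were set down before their results were seen. The splits by whole times were chosen after the planned splits were seen. The one-way explanation of the DD peaks was narrowed to a change going on to ZT20, and the test of a step complete by ZT16 was added, after the result for ZT20 against ZT8 had been seen.

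Rhythmic IDs next to each other in ID order peaked at like times more often than random pairs. The hypothesis was that neighbours share their peak time. In LD 25.9% of 7359 adjacent pairs of rhythmic IDs peaked within 2 h of each other, against a mean of 17% and a highest value of 18.8% in 10000 random pairings (permutation p = 1e-04, the smallest they can give). In LL the share was 26.8% of 1203 pairs against 17.5%, and in DD 34.4% of 1342 pairs against 22.3%. This is in line with the hypothesis. ID order only stands in for position, and neighbours that are copies of each other, or overlap and share reads, could give the same excess.

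Some IDs in DD were at full level at some times and had at most 1 read per time at others, in both replicates. There were 44 such IDs in DD, with a median of 47.4 reads expected at the silent times, against 13 in LD and 17 in LL, and 27 of the 44 (61.4%) were detected in all 24 LD and LL libraries. Of the 13 in LD 0 and of the 17 in LL 1 (5.88%) were detected in all 24 libraries of the other regimes. Depth was not matched here. With median gene counts of 10620768 in LD, 2531508 in LL and 2115978.5 in DD, at most 1 read is a stricter rule in LD. The LD IDs reached 1.355 to 29.07 CPM at their highest time, so low ones could be missed in shallower libraries. The contrast of DD with LD is thus not like for like. Plants of another genotype at some times of the DD series may be a source, since such IDs would then lie in blocks: 18 of the 44 had a neighbour with the same silent times within 50 tested IDs, against a mean of 1.22 and a highest value of 11 in 10000 random placements (permutation p = 1e-04, the smallest they can give). LD showed an excess as well, from a single run of 3 IDs on MH11, with 3 of 13 against a mean of 0.0546 (permutation p = 2e-04), and LL had 2 of 17 against 0.496 (permutation p = 0.2). MH04g0100000, named among the largest DD rhythms, is among 6 IDs on MH04 that were silent at ZT0, ZT4 and ZT8. MH06g0057800, also named there, had 3 counts at ZT0 and 1 at ZT4, too many for the 44, and lies among 4 IDs on MH06 that were silent at these times. MH10g0395300, named for LL, is among the 17 in LL. Of these 17, 11 were silent at both ZT0 and ZT4, MH10g0395300 among them, and they spread from MH02 to MH11. A test of nearness does not see silent times shared by distant IDs. In DD 19 of the 44 and in LD 6 of the 13 were silent at both ZT0 and ZT4. Random placements do not keep the like timing of neighbouring rhythmic IDs, and 37 of the 44 in DD were called rhythmic. Neighbours that are copies of each other, or overlap and share reads, could also give such an excess. The excess therefore does not single out another genotype. A rhythm or a regional change of expression in constant dark was not tested and stays open.

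Replicates differed far more in LD than in LL and DD. Deeper sequencing of LD is argued against, since at equal depth the lowest chi-square per degree of freedom of an LD pair was 5.494 and the highest of an LL or DD pair was 1.873. Library repeats of a single plant sample in LL and DD are a candidate explanation. At equal depth, 101 IDs over the 6 LD pairs had at least 20 reads in a replicate and at most 1 in the other, against 1 in LL and 0 in DD. This cannot be told apart from LD plants that differ more among themselves, because every library of a regime shares its handling, and an effect of the light regime stays open and untested.

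The fitted peaks of DD rhythmic IDs gathered at ZT0 to ZT4 and at ZT12 to ZT16. By the time of the highest mean the gathering was weaker, with 11.3% at ZT12 and 22.8% at ZT16 against 12.0% and 23.4% in LL. A one-way change going on to ZT20 is left open. The typical one of these 2798 IDs lay at ZT20 within -0.0768 of its range of its ZT8 level, but choosing IDs by these peaks places both times near the middle of a fitted curve, and LD gave -0.0974. A linear trend in the cosinor regression took the rhythmic calls from 3593 to 1255 in DD, from 10017 to 7798 in LD and from 3248 to 2385 in LL. A trend also takes up part of a true cycle with such peaks. Plants of another genotype are left open. These IDs lay near on-off IDs only 1.08 times as often as LD rhythmic IDs (95% CI 0.977 to 1.18). That argues against an effect confined to the surroundings of on-off IDs. It cannot decide on an effect on IDs elsewhere, and the on-off IDs themselves were left out. A step complete by ZT16 is left open as well: at ZT20 the typical ID had moved back towards its peak level by 0.22 of its range (0.205 to 0.232), between the bounds of under 0.1 for a step and over 0.25 for a cycle, and LD gave 0.21. With a single cycle sampled, a rhythm of expression in constant dark may be the source and was not tested further.

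Other circular orders of the 6 times gave fewer rhythmic calls in most cases. Of 60 orders, 1 reached the real 11326 in LD, with 10696 as the highest other, 2 reached the real 4397 in LL, with 4622 as the highest other, and 2 reached the real 4666 in DD, with 4760 as the highest other. In each regime a share under 0.05 of orders reached the real count, which argues against an arbitrary order of the times as its source. In LL and DD, however, another order gave more calls than the real order. The median of the other orders was 7485 in LD, 2277 in LL and 1963 in DD, so many calls arise without the real order. A drift or step over the single cycle would also favour the real order, so these orders cannot tell it from a daily rhythm. For levels, 1 of 100 planned splits within times reached the real 13938 in DD against LD (highest other 12559) and the real 12681 in LL against LD (11421), but mixed groups have a larger replicate spread there. With both libraries of a time exchanged together, 1 of 32 splits reached 13938, with 12064 as the highest other and a median of 7224. For LL against LD 1 of 32 reached 12681, with 10885 and 6201. By these splits chance can be excluded at a share under 0.05 for both, where 1 of 32 is the smallest share they can give. An effect of handling, depth or replicate spread shared by a regime's libraries is not excluded.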
